A study of Mus musculus with 15 samples.

How the data were processed

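The series holds 15 RNA-seq libraries of mouse OT-II CD4 T cells in 5 groups of 3, as described in the results. Per the labels' protocols, RNA was extracted from sorted cells with a column kit, amplified as whole transcriptome cDNA in 13 PCR cycles and made into libraries with a transposase kit. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.36, STAR 2.7.3a and featureCounts of Subread 1.6.5, with the genome build mm10. The authors deposited 1 table of raw counts per gene for 49492 genes, without normalization, with exon positions and with each gene's summed exon length in bases. The annotation release is not given in the sources used here. Of the symbols, 47240 were found in GENCODE M21 on the same build, and 99.95% of those overlapped that gene's position. Coordinates are those of the deposited table.

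The table itself shows how reads were counted. Of genes lying wholly inside the exons of another well expressed gene, 105 of 107 on the same strand and 134 of 137 on the opposite strand still had counts, so reads over overlapping genes entered the count of each of them and strand was not evidently used. Even numbers made up 61 to 69.5% of counts from 1 to 20, so the mates of a pair may have been counted one by one, and counts are not taken as numbers of fragments. Overlapping, antisense and near-identical genes cannot be separated, and the results name the overlapping ones among the genes they report.

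Groups and replicate numbers came from the sample titles. Totals per library ran from 38082967 to 99380475, and 19260 to 21331 genes had counts. Pairs of replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 42.6 to 650.5), so no library was taken as a duplicate. Genes were kept with edgeR's filterByExpr at a minimum count of 10, leaving 19942. Libraries were scaled by TMM, and CPM values are counts divided by the scaled library size, in the usual unit of edgeR. One negative binomial model over all 15 libraries with a term per group was fitted with edgeR's quasi-likelihood functions (robust), and each comparison was a contrast of group terms, Benjamini-Hochberg adjusted over the genes tested with a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic. Recipient and subset averages weight both levels equally, and the interaction is the difference of subset differences. Where a group had no counts for a gene, the fold is a bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact 95% Poisson interval.

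Gene lists (24) were fixed before the data were examined. They cover lymphoid homing and quiescence, Th2, Tfh, Th1 and cytotoxic, Th17, regulatory T cell, coinhibitory receptor, G1/S, G2/M, early T cell receptor response, type I interferon response, effector migration and cytoskeleton, glycolysis, oxidative phosphorylation, cholesterol synthesis, BCL2 family and Fas, and heat shock genes, and markers of B cells, plasma cells, dendritic cells and macrophages, neutrophils, CD8 and NK cells, erythroid cells, and stromal and endothelial cells. They were tested with camera at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 5 tested genes were not tested. The naming rule was fixed at the same time. It took, among others, Cd44, Batf3, Bcl6, Gata3, Tbx21, Foxp3, Tcf7 and Prdm1 in every comparison whatever their values, and Il4, Il13, Il21, Ifng, Il2ra, Cxcr5, Ccr7 and S1pr1 where called. It added the 8 largest changes per direction (5 against naive cells) among called genes with separated groups and at least 5 CPM in the higher group, leaving out gene models, pseudogenes, variable segments, mitochondrial, ribosomal and small RNA genes, and the 2 most significant members of each list per direction. Some genes that the rule took are not reported here.

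On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 19942, the fit recovered 33 and 65 for the WT subset comparison with 7 false calls, 36 and 61 for the recipients in CD62L- cells with 3, 46 and 72 for the recipient average with 4, and 29 and 52 for WT CD62L- against naive cells with 5. Of 5 shifted lists camera called 5 in each, and of 15 unshifted lists at most 1. The simulated genes varied independently of each other, so this says nothing about false calls in lists whose genes vary together. The heat shock list, for example, had an estimated correlation of 0.408 in the recipient average.

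Alternatives were RLE size factors, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 20), DESeq2's Wald test, limma's voom with library quality weights, a fit of the groups compared only, a replicate block, and each library left out in turn. Added after the data were seen were a fit without the third WT CD62L- and the third Batf3-/- CD62L- libraries (low depth, high ribosomal RNA share) and one without 3 ribosomal RNA locus genes. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.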

Results

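RNA was sequenced from mouse CD4 T cells that carry the OT-II receptor, a transgenic T cell receptor specific for a peptide of ovalbumin (OVA). Naive OT-II cells, marked by the congenic antigen CD45.1, were transferred into wild-type (WT) or Batf3-/- recipients. Batf3 is a transcription factor needed for the development of type 1 conventional dendritic cells. Only the recipients, not the transferred donor cells that were sequenced, lacked the gene. The recipients were given 60 µg OVA with 30 µg papain, a cysteine protease that primes type 2 responses, into the nose in 3 doses, starting 24 hours after transfer. On day 5, activated (CD44 high) donor cells of the lung-draining mediastinal lymph node were sorted into CD62L- and CD62L+ cells. CD62L is the adhesion receptor that takes T cells into lymph nodes. Naive OT-II cells of untreated mice were the control. Each of the 5 groups had 3 libraries, 15 in all, and the deposited gene counts summed to between 38082967 and 99380475 per library. The labels call the libraries independent replicates without tying them to animals, so the p-values measure the spread between these libraries. Batf3 itself was close to silent in the sequenced cells, with 49 counts over the 15 libraries and at most 20 in one, and its level says nothing about the recipients.

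Naive and primed cells separated along the first principal component, which held 34.6% of the variance over 19942 genes. Spearman correlations between libraries were 0.96 to 0.979 within a group, 0.949 to 0.98 between primed groups and 0.908 to 0.928 between naive and primed libraries. The libraries also varied in technical quantities. Counts on ribosomal RNA loci took 3.82 to 5.19% of the library numbered 1 in each group and 8.12 to 16.4% of the others. The share of mitochondrial counts went with the subset. It ran from 1.38 to 2.37% in WT CD62L- and from 0.81 to 1.16% in WT CD62L+ libraries, and from 1.65 to 2.2% and from 0.76 to 1.58% in those of Batf3-/- recipients. Within a single recipient type, chance separates 3 from 3 libraries in this way in 10% of cases. Ribosomal protein genes took 2.91 ± 0.118% in WT CD62L- against 3.687 ± 0.396% in WT CD62L+ libraries, without overlap, and 3.39 ± 0.26% against 3.913 ± 0.256% in Batf3-/- recipients, with overlap. Neither share was a term in a fit, so the subset comparisons are not adjusted for them. The third WT CD62L- library had the lowest total and stood apart on the second component at -138, against -49.9 for the next lowest. The other WT CD62L- libraries lay at -27.5 and -49.9, also below every library of other groups (lowest -12.5). WT CD62L- totals (38082967 to 64938211) lay below those of Batf3-/- CD62L- (from 77620291) and overlapped those of WT CD62L+ libraries (from 61645012). Genes with counts ran from 19260 to 19942, against 20060 to 20805 and 20374 to 20991 in these groups. Depth entered the main fit only as scaling, so its effects cannot be told apart in comparisons of WT CD62L- cells.

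The first question was how OT-II cells primed through the airway differed from naive ones. The naive cells came from untreated mice, while the primed ones were transferred and sorted as CD44 high from the mediastinal node. Effects of transfer, host and sort cannot be told apart from those of priming in these comparisons. In WT CD62L- cells the T follicular helper (Tfh) genes stood far above the naive level. Cxcr5, the chemokine receptor that directs cells to B cell follicles, averaged 308 ± 26 CPM (read counts scaled to library size; SD, n = 3) against 3.86 ± 0.47 in naive cells. Bcl6, the transcription factor of Tfh cells, averaged 121 ± 8.8 against 24.5 ± 3.9 CPM. Il21, a Tfh cytokine that acts on B cells, reached 104 ± 13 CPM and had only 2 counts over the 3 naive libraries. Of the Tfh list, 17 of 18 tested genes rose and 1 fell. The activation marker Cd44 was 10.6-fold higher (log2 fold change 3.41, SE 0.17, adjusted p = 3e-09). Most cell division genes rose, with all 19 G2/M genes and 14 of 19 G1/S genes called higher, while 2 G1/S genes, Cdt1 and Gins2, fell. Type I interferon response genes went the other way, with 16 of 22 called lower and 2 higher.

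In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 6004 genes between WT CD62L- and naive cells, 3370 higher and 2634 lower. Gna14 (20.7 ± 3 CPM), Cela1 (17.5 ± 2) and Il1r1 (24 ± 8.1), the receptor for interleukin 1, had no counts in naive cells. Against a floor of 3 counts over the naive group they were at least 1860-fold, 1590-fold and 2000-fold higher. Sostdc1, a secreted antagonist of BMP and Wnt signalling, had 2 naive counts, a ratio of 9100 with a counting interval of 2520 to 75200. Il21 gave a ratio of 13600 (interval 3760 to 112000). Among the genes highest in naive cells, Dntt, the terminal transferase of antigen receptor rearrangement, fell from 100 ± 10 CPM to 2 counts in the WT CD62L- group, a ratio of 8160 (interval 2260 to 67300). Acoxl, Adamts14, Hoxa7 and Tbc1d16 had no counts in WT CD62L- cells and were at least 664-fold, 607-fold, 341-fold and 343-fold lower. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

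Type 2 genes were also higher in WT CD62L- than in naive cells, 11 of 14 listed ones against 1 that fell. Il4 averaged 30 ± 1.4 CPM against 0.0592 ± 0.043, and Il17rb, a subunit of the interleukin 25 receptor, 66.3 ± 6.1 against 3.26 ± 0.83. Gata3, the type 2 transcription factor, rose 2.25-fold (adjusted p = 7.55e-06). Il13 had 24 counts in 1 WT CD62L- library and was below the expression filter. The coinhibitory receptor list had 9 of 10 genes higher, the regulatory T cell list 9 of 14 higher and 2 lower, and the effector migration list 13 of 19 higher and 4 lower. Foxp3 itself fell 2.09-fold (adjusted p = 0.00178). Tbx21, the type 1 transcription factor, rose from 0.137 ± 0.12 to 3.85 ± 0.37 CPM (adjusted p = 0.000219), while Prdm1 did not pass (adjusted p = 0.0692). Genes of lymphoid homing and quiescence were mostly lower, 11 of 16 with 1 higher. Tcf7, a member of that programme, rose 1.68-fold. Among other cell types' markers, 6 of 7 tested erythroid genes fell, and their summed level was 630.5 ± 53.2 CPM in naive and 74.81 ± 26.8 CPM in WT CD62L- cells.

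The list tests against other genes (camera, preset correlation) called 17 of 23 lists between WT CD62L- and naive cells, and 14 of them held with an estimated correlation. Oxidative phosphorylation, with 11 of 20 genes higher, had an adjusted p = 0.00859 and 0.212 with an estimated correlation. The Th1 and cytotoxic list (7 of 17 higher, 2 lower) had 0.02 and an adjusted p = 0.0568 with an estimated correlation, and the erythroid list 0.001 and an adjusted p = 0.129 with an estimated correlation.

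The same comparison for the other primed groups called 5430 genes in WT CD62L+ cells (3160 higher, 2270 lower), 5843 in Batf3-/- CD62L- cells (3286 and 2557) and 6020 in Batf3-/- CD62L+ cells (3367 and 2653). Cxcr5 averaged 123 ± 2, 252 ± 18 and 114 ± 6.3 CPM in these groups, and Il21 26.5 ± 3.8, 83.5 ± 6.7 and 37.2 ± 5.8 CPM. Prdm1, a regulator of effector differentiation that represses Bcl6, passed in these 3 comparisons and was lower, at 0.258 ± 0.25, 0.429 ± 0.52 and 0.229 ± 0.2 CPM against 11 ± 2 in naive cells. All 19 G2/M genes rose in each of the 3 groups. Of the interferon list, 16, 15 and 16 of 22 genes fell. Of the B cell markers, 12 of 16 were higher than in naive cells in both CD62L+ groups, 11 were lower in WT CD62L- cells and 2 were lower in Batf3-/- CD62L- cells. These comparisons share the naive libraries and are not compared with each other here.

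The second question was how CD62L- cells differed from CD62L+ cells of the mediastinal lymph node. The labels do not say whether libraries of both subsets came from the same animals, and the main fit did not pair them. In WT recipients the CD62L- cells had the higher levels of Tfh and coinhibitory genes. Cxcr5 was 2.5-fold higher (log2 fold change 1.32, SE 0.1, adjusted p = 6.09e-06), Bcl6 2.35-fold (1.23, SE 0.12, adjusted p = 8.81e-05) and Il21 3.91-fold (1.97, SE 0.18, adjusted p = 3.3e-05). The coinhibitory receptor Tigit rose from 45.6 ± 8.6 to 373 ± 62 CPM and Cd160 from 9.4 ± 2.6 to 82.5 ± 7.8 CPM. Il4 rose from 3.66 ± 0.7 to 30 ± 1.4 CPM. Cd44 was 256 ± 36 against 230 ± 21 CPM and did not pass (adjusted p = 0.785).

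The test called 244 genes in WT recipients, 134 higher and 110 lower in CD62L- cells, and 122 of them differed at least 2-fold. Of 18 tested Tfh genes, 5 rose and none fell over all genes tested, and 10 rose when adjusted over the list alone. The Tfh list as a whole was higher (camera adjusted p = 7.55e-21, 0.000105 with an estimated correlation). Besides Tigit, Cd160 and Il4, the 8 largest increases were Padi4, which citrullinates histones (14.2-fold, adjusted p = 3.3e-05), Asb2 (11.3-fold), Klhl4 (10.6-fold), Il1r1 (10.3-fold, adjusted p = 0.00157) and Sostdc1 (8.01-fold, adjusted p = 6.09e-06). Il1r1 was the 1 called member of the Th17 list, which passed with camera (adjusted p = 0.00435) and missed with an estimated correlation (adjusted p = 0.0812). Il4 was the called member of the Th2 list (3 of 14 adjusted over the list alone, camera adjusted p = 0.000945, 0.0135 with an estimated correlation), and Gata3 did not pass (404 ± 25 against 441 ± 68 CPM, adjusted p = 0.781). Tbx21 (adjusted p = 0.734), Foxp3 (0.86), Prdm1 (0.373) and Tcf7 (0.287) did not pass either.

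Genes of lymphoid homing and quiescence were lower in WT CD62L- cells, 5 of 16 called and 7 adjusted over the list alone (camera adjusted p = 3.32e-11, 0.00519 with an estimated correlation). These included Dapl1 (4.41-fold lower, adjusted p = 2e-06), Igfbp4 (4.72-fold lower, adjusted p = 0.00649) and S1pr1, the receptor for exit from lymphoid organs (192 ± 48 against 328 ± 13 CPM, adjusted p = 0.0104). Nrp1 fell 1.94-fold, and Myc, a driver of cell growth, 1.61-fold. In the migration list S100a11 rose 2.4-fold while Itgb1 and Itgb7, integrin subunits, fell 2.11-fold and 1.38-fold. Fas, a death receptor, rose 1.72-fold and Bcl2l1, which encodes the survival protein BCL-XL, fell 1.47-fold. Cmpk2 was the 1 called interferon response gene, 2.41-fold higher. That list passed with camera (adjusted p = 0.0062) but not with an estimated correlation (adjusted p = 0.184). The same held for the G2/M list, lower with no single gene called (0.0225, and adjusted p = 0.355 with an estimated correlation), and the heat shock list, also lower with none called (0.0229, and adjusted p = 0.453 with an estimated correlation). The coinhibitory list was higher (2 of 10 called, adjusted p = 3.44e-06, 0.0135 with an estimated correlation).

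B cell transcripts were the largest group on the other side. In WT recipients 12 of 16 B cell markers were lower in CD62L- than in CD62L+ cells (14 adjusted over the list alone), with a median log2 fold change of -3.03 (camera adjusted p = 6.05e-77, 1.48e-05 with an estimated correlation). Cd79a, a subunit of the B cell receptor, averaged 3.52 ± 0.48 against 30 ± 6.3 CPM, and 11.7 ± 1.1 CPM in naive cells. Cd74, the invariant chain, averaged 42.7 ± 6.5 against 277 ± 34 CPM. Among the 8 largest decreases by the naming rule were Fcmr, Cr2, Ly6d, Fcer2a, H2-Ab1, H2-Aa (8.62-fold) and Cd79a (8.52-fold), all known from B cells, with H2-Ab1 and H2-Aa also expressed by other antigen-presenting cells. The dendritic cell and macrophage list was not called with camera (15 genes tested, adjusted p = 0.569). In the plasma cell list only Igkc was called lower (3.79-fold, adjusted p = 0.0144). Read sharing limits Cd74, whose exons hold the microRNA gene Mir5107.

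The WT count was 139 without the second and 121 without the third WT CD62L+ library, 265 without the first WT CD62L- library, 121 in a fit of these 6 libraries only, 529 with the replicate number as a term (replicate block), 476 with limma's voom and library weights, and 824 with DESeq2, which called all 244.

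In Batf3-/- recipients the Tfh genes Cxcr5, Bcl6 and Il21 were again higher in CD62L- cells. Cxcr5 was 2.2-fold higher (log2 fold change 1.14, SE 0.1, adjusted p = 6.3e-05), Bcl6 1.81-fold (0.86, SE 0.12, adjusted p = 0.00441) and Il21 2.25-fold (1.17, SE 0.17, adjusted p = 0.00667). Il4 rose from 1.64 ± 0.58 to 10.9 ± 2.6 CPM and Tigit from 25.9 ± 6.6 to 178 ± 27 CPM. Cd44 did not pass (adjusted p = 0.657). The test called 100 genes, 57 higher and 43 lower, of which 49 differed at least 2-fold. The largest increases were Padi4 (13.4-fold), Tigit (6.86-fold), Il4 (6.65-fold), Sostdc1 (5.55-fold), H2-Q2 (4.52-fold), Sccpdh (4.07-fold), Coro2b (4.04-fold) and Cela1 (3.16-fold). H2-Q2 is a class I gene of a family with near-identical members, so its value is uncertain. Of 18 Tfh genes 4 rose (8 rose and 1 fell adjusted over the list alone), and the list was higher (camera adjusted p = 4.4e-15, 0.000417 with an estimated correlation). Of 16 B cell markers, 9 were lower (14 adjusted over the list alone, median log2 fold change -2.15, camera adjusted p = 6.41e-65, 1.42e-05 with an estimated correlation), with Cd79a at 6.29 ± 0.79 against 36.5 ± 7 CPM. The largest decreases again held B cell genes, Ly6d, Iglc2, Cd79a, H2-Ab1, Spib, H2-Aa, Fcmr and Ms4a1.

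Among the other lists in Batf3-/- recipients, lymphoid homing and quiescence was lower (camera adjusted p = 1.91e-05, and adjusted p = 0.0521 with an estimated correlation). Of its 16 genes 1 was called, Dapl1 (2.27-fold lower), and 5 were lower and 1 higher adjusted over the list alone. Interferon response genes were higher with none called (2.51e-05, and adjusted p = 0.0521 with an estimated correlation). Heat shock genes were lower with Hspd1 called (1.43-fold, 2.25e-06, and adjusted p = 0.128 with an estimated correlation). Lists lost in the same way were oxidative phosphorylation (lower, 0.0076, and adjusted p = 0.316 with an estimated correlation), coinhibitory receptors (higher, 2 of 10 called, 0.00802, and adjusted p = 0.129 with an estimated correlation) and Th2 (higher, 0.0204, and adjusted p = 0.0991 with an estimated correlation). S100a11 rose 1.99-fold and Cd160 2.17-fold, and Nrp1 fell 1.65-fold. Of Bcl6, Gata3, Tbx21, Foxp3, Prdm1 and Tcf7, Bcl6 alone passed. The count was 43, 46 and 51 without the first, second or the third Batf3-/- CD62L- library, and 39, 32 and 41 without those of the CD62L+ group. It was 26 in a fit of these 6 libraries only, 55 without the 2 libraries that stood apart, 197 with the replicate block, 335 with voom and 432 with DESeq2.

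The subset differences of the recipients went together. No libraries are shared between these comparisons, and 44 genes were called higher in CD62L- cells in both recipients and 24 lower, against 0.383 and 0.237 for independent lists of those sizes. Averaged over recipients, 590 genes were called, 305 higher and 285 lower, and 193 differed at least 2-fold. The average added Ifng (2-fold higher, adjusted p = 0.0252), the type 2 receptor gene Il17rb (1.6-fold higher, adjusted p = 0.0165), Tnf (1.58-fold higher), Tcf7 (1.21-fold higher, adjusted p = 0.0398) and Cebpa (11.9-fold higher). It also added Ccr7, the receptor for T zone chemokines (1.74-fold lower, adjusted p = 0.0382), Irf4 (1.5-fold lower) and Runx3 (1.51-fold lower). Of the lists, 9 of 18 Tfh genes, 2 of 14 Th2 genes and 3 of 22 interferon genes rose with none falling. Of the homing list 6 of 16 fell and 1 rose, and of the heat shock list 5 of 10 fell, among them Hspe1 (1.4-fold) and Hspd1 (1.29-fold). The interferon list kept its call with an estimated correlation (adjusted p = 0.0456), and the heat shock list did not (adjusted p = 0.189 with an estimated correlation). Neither did Th17 (higher, 0.0193, and adjusted p = 0.14 with an estimated correlation) nor oxidative phosphorylation (lower, 0.0412, and adjusted p = 0.49 with an estimated correlation). The count was 388 without the second Batf3-/- CD62L+ library, 985 with the replicate block, 1099 with voom and 1259 with DESeq2.

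**Figure D1:**
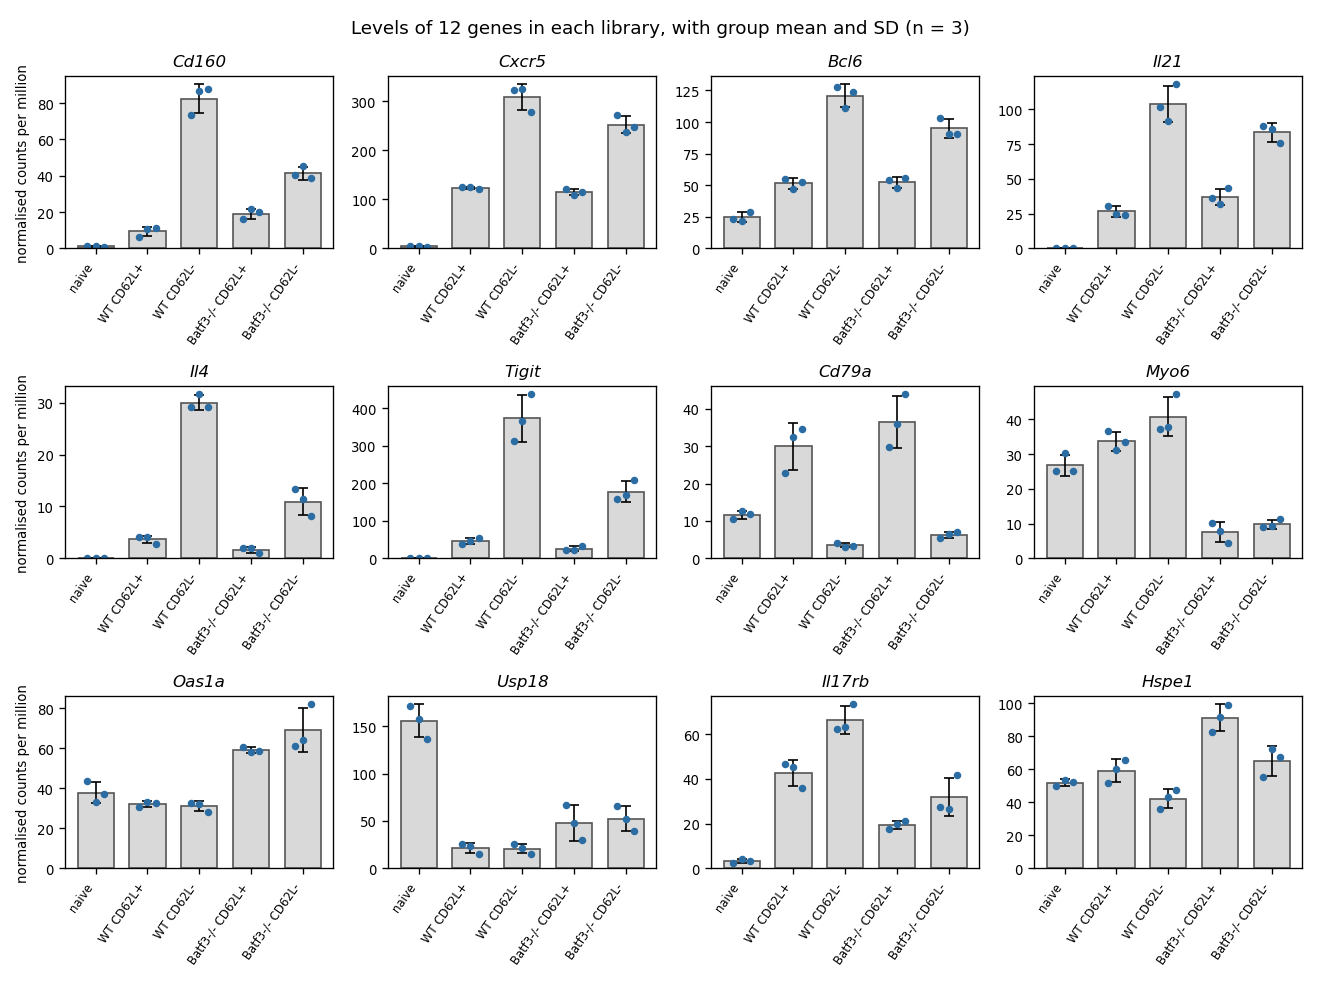
Normalised read counts in CPM (vertical axes, linear from 0) of 12 genes in the 5 groups (horizontal axes). Bars are group means, error bars the SD of 3 libraries and points the libraries. Tigit averaged 373 CPM in WT CD62L- cells and 45.6 CPM in WT CD62L+ cells, and Myo6 averaged 7.48 and 9.86 CPM in the Batf3-/- groups against 33.7 and 40.8 CPM in the WT groups.

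The third question was what the recipient's lack of Batf3 changed in the donor cells. Averaged over subsets, cells from Batf3-/- recipients had higher levels of interferon response and heat shock genes and lower levels of type 2 and migration genes. Myo6, an actin-based motor, showed the clearest difference. It averaged 7.48 ± 2.9 and 9.86 ± 1.3 CPM in CD62L+ and CD62L- cells of Batf3-/- recipients, 33.7 ± 2.8 and 40.8 ± 5.6 CPM in those of WT recipients and 26.8 ± 3 CPM in naive cells (4.32-fold lower, log2 fold change -2.11, SE 0.17, adjusted p = 0.00012). Il4 was 2.48-fold lower (-1.31, SE 0.23, adjusted p = 0.0256) and Il17rb 2.14-fold lower (-1.1, SE 0.14, adjusted p = 0.00614). Oas1a, an interferon-induced sensor of double-stranded RNA, was 2.03-fold higher (1.02, SE 0.09, adjusted p = 0.000292), and Usp18, a feedback inhibitor of interferon signalling, 2.38-fold higher (1.25, SE 0.2, adjusted p = 0.0136).

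The average over subsets called 88 genes, 54 higher and 34 lower in Batf3-/- recipients, and 24 differed at least 2-fold. Of 22 interferon response genes, 6 rose and none fell (15 adjusted over the list alone, camera adjusted p = 5.9e-22, 0.000267 with an estimated correlation). They included Oasl2, Oasl1, Ifi44 and Isg15, and outside the list Ifit3b rose 2.4-fold. Their primed levels stayed under the naive level for several of them, with Usp18 at 48.2 ± 19 and 52.3 ± 13 CPM in Batf3-/- groups, 21.1 ± 5.3 and 20.9 ± 5 in WT groups and 156 ± 17 in naive cells. Oas1a is one of a cluster of similar genes and its value is uncertain to that extent. All 10 heat shock genes lay above 0 and 5 passed (10 adjusted over the list alone, camera adjusted p = 1.7e-21, 0.00466 with an estimated correlation). Hspe1, a mitochondrial chaperonin, was 1.54-fold higher (adjusted p = 0.0126). The near-identical pair Hspa1a and Hspa1b was 2.95-fold and 3.28-fold higher, with a wide spread, Hspa1a at 155 ± 87 CPM in Batf3-/- CD62L- cells against 48 ± 11 in WT ones. Hspe1 and Hspd1 overlap only at their ends, on opposite strands (chromosome 1, 55088132 to 55088243). Reads in that stretch cannot be told apart. Myc was 1.52-fold higher (adjusted p = 0.0126).

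Among genes lower in cells from Batf3-/- recipients, the type 2 list had Il4 and Il17rb called and 7 of 14 adjusted over the list alone (camera adjusted p = 1.95e-12, 0.00018 with an estimated correlation). Gata3 averaged 350 ± 39 and 318 ± 36 CPM against 441 ± 68 and 404 ± 25 and did not pass (adjusted p = 0.139). The migration list had 4 of 19 called and 13 adjusted over the list alone, all lower (camera adjusted p = 5.22e-16, 0.00018 with an estimated correlation). Anxa2, a membrane-binding annexin, fell 1.56-fold (adjusted p = 0.00592), and Selplg, the P-selectin ligand, 1.24-fold (adjusted p = 0.0221). Il7r, the receptor of the survival cytokine interleukin 7, was 1.88-fold lower (adjusted p = 0.00676) and Tigit 1.92-fold (adjusted p = 0.0412). Sytl2, Cela1 and Mpp4 fell 2.17-fold, 2.32-fold and 2.09-fold, and Mpp4 shares reads with another gene on the same strand. Neither Cd44 (adjusted p = 0.075), Bcl6 (0.489), Tbx21 (0.635), Foxp3 (0.669), Prdm1 (0.664) nor Tcf7 (0.533) passed.

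Markers of other cells moved with the recipient too. B cell markers were higher in Batf3-/- recipients (1 of 16 called and 9 adjusted over the list alone, camera adjusted p = 2.55e-09, 0.013 with an estimated correlation). The difference lay in CD62L- cells (median log2 fold change 1.06, camera adjusted p = 8.5e-14). In CD62L+ cells the median was 0.13 and the list was not called (camera adjusted p = 0.253). The erythroid list was lower with no gene called over all genes tested and 5 of 7 adjusted over the list alone (camera adjusted p = 2.91e-07, and adjusted p = 0.0506 with an estimated correlation). Smaller list calls were lost with an estimated correlation. These were G1/S genes (0.0296, and adjusted p = 0.152 with an estimated correlation), early genes induced by the T cell receptor (0.0339, and adjusted p = 0.381 with an estimated correlation), oxidative phosphorylation (0.0339, and adjusted p = 0.362 with an estimated correlation), cholesterol synthesis (lower, 0.0296, and adjusted p = 0.156 with an estimated correlation) and Th17 genes (0.0146, and adjusted p = 0.139 with an estimated correlation). The count of 88 genes was 132 without the first WT CD62L- library, 57 without the second or the third WT CD62L- library, 36, 51 and 42 without the first, second or the third WT CD62L+ library, 44 without the second Batf3-/- CD62L- library, and 39 and 37 without the second or the third Batf3-/- CD62L+ library. It was 38 without the 2 libraries that stood apart, 201 with the replicate block, 327 with voom and 620 with DESeq2, which called all 88.

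Within CD62L- cells alone 10 genes differed between recipients, 5 in each direction. Oas1a (2.24-fold, adjusted p = 0.00413), Dapl1 (2.02-fold, adjusted p = 0.0126) and the creatine kinase gene Ckb (2.11-fold, adjusted p = 0.0331) were higher in Batf3-/- recipients. Myo6 (4.13-fold, adjusted p = 0.00413), H2-Q2 (1.98-fold, adjusted p = 0.00413), the signalling paracaspase Malt1 (1.66-fold, adjusted p = 0.0289), Art2b (1.7-fold, adjusted p = 0.0289) and Rgs1 (1.84-fold, adjusted p = 0.0331) were lower. Also called was Wdfy4, which the naming rule did not take and which was named after its value was seen (higher, adjusted p = 0.0289). The list tests kept with an estimated correlation were interferon response (adjusted p = 0.00264) and B cell markers (0.00345), both higher, and Th2 (0.00159) and migration (0.00268), both lower. Heat shock (higher) had an adjusted p = 0.0532 with an estimated correlation. Tfh (lower, 0.0263, and adjusted p = 0.143 with an estimated correlation), coinhibitory (lower, 0.00935, and adjusted p = 0.142 with an estimated correlation), cholesterol synthesis (lower, 0.00691, and adjusted p = 0.116 with an estimated correlation) and erythroid genes (lower, 0.00177, and adjusted p = 0.203 with an estimated correlation) were lost too. The count was 31 without the first, 5 without the second and 5 without the third WT CD62L- library, and 4 without the second Batf3-/- one. It was 0 in a fit of these 6 libraries only (1082 genes at an unadjusted p under 0.05), 74 with the replicate block, 79 with voom and 431 with DESeq2.

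Within CD62L+ cells only Myo6 passed, 4.51-fold lower in Batf3-/- recipients (log2 fold change -2.17, SE 0.24, adjusted p = 0.00655). Of the lists, interferon response (0.00107), heat shock (0.00375) and Th17 (0.0247) were higher and Th2 (0.00107) and migration (0.000367) lower at these adjusted p with an estimated correlation. Camera calls lost in this way were erythroid (lower, 3.85e-07, and adjusted p = 0.0505 with an estimated correlation), homing (lower, 0.00387, and adjusted p = 0.121 with an estimated correlation), G2/M (lower, 0.00745, and adjusted p = 0.233 with an estimated correlation) and stromal genes (lower, 0.0417, and adjusted p = 0.117 with an estimated correlation). So were G1/S (higher, 0.0047, and adjusted p = 0.0682 with an estimated correlation), oxidative phosphorylation (higher, 0.00529, and adjusted p = 0.238 with an estimated correlation), early T cell receptor genes (higher, 0.032, and adjusted p = 0.379 with an estimated correlation) and plasma cell genes (higher, 0.0433, and adjusted p = 0.238 with an estimated correlation). None of the Th17 genes was called over all genes tested. No gene was called without the second Batf3-/- CD62L+ library (1023 at an unadjusted p under 0.05) or in a fit of these 6 libraries only (1222). There were 5 calls with no filter and 5 with a stricter one, 32 with the replicate block, 70 with voom and 142 with DESeq2.

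The test of whether the subset difference itself depended on the recipient called 0 genes with edgeR, with 860 at an unadjusted p under 0.05 where 997 are expected by chance. DESeq2 called 36, voom 1 and the replicate block 1, and edgeR called 2 without the third Batf3-/- CD62L- library.

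Libraries with the same number shared features, so the number was also fitted as a term. With this replicate block 243 of the 244, 99 of the 100, 579 of the 590, 10 of the 10, 1 of the 1 and 87 of the 88 genes called between primed groups were called again, as were 5891 of the 6004, 5324 of the 5430, 5730 of the 5843 and 5920 of the 6020 genes called against naive cells. Exons of Anxa2, Bcl6, Cd160, Cebpa, Foxp3, Gata3, Gins2, Hoxa7, Hspa1a, Iglc2, Il21, Nrp1, Oasl1, Tbc1d16 and Usp18 overlap those of another annotated gene with counts, and their values are uncertain to that extent. On mm10, Cxcr5 lies on chromosome 9 from 44511787 to 44561877, Bcl6 on chromosome 16 from 23965052 to 23988852, Il21 on chromosome 3 from 37222759 to 37232636, Il4 on chromosome 11 from 53602982 to 53618669, Cd79a on chromosome 7 from 24897381 to 24902197, Myo6 on chromosome 9 from 80165031 to 80311729, Oas1a on chromosome 5 from 120896256 to 120907521 and Il17rb on chromosome 14 from 29996141 to 30008896. The counts are over the annotated exons of each gene.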

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

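The tests of the B cell marker pattern and the counts over other splits of the libraries were chosen after the results were seen.

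The subset differences of 5 lists differed between recipients when that difference was tested itself. With camera at the preset correlation, the drop of lymphoid homing and quiescence genes from CD62L+ to CD62L- cells was smaller in Batf3-/- recipients (adjusted p = 0.00485, 15 of 16 genes on that side). The rises of Tfh genes (adjusted p = 0.0159, 13 of 18), Th17 genes (0.00485, 7 of 9) and coinhibitory receptors (0.0133, 8 of 10) in CD62L- cells were smaller there too in most genes. So was the drop of B cell markers (1.2e-09, 14 of 16). The mean over the list went the other way for Tfh genes (0.13 on the log2 scale, median -0.1) and coinhibitory receptors (0.46, median -0.19). With an estimated correlation the first 4 lists were not called (adjusted p = 0.175 each), and the B cell list was (0.0442). With fry none was called (adjusted p = 0.215, 0.215, 0.215, 0.452 and 0.0589 in the order given). No single gene was called by this test with edgeR, with 860 at an unadjusted p under 0.05, 36 called with DESeq2 and 1 with voom. The Tfh and coinhibitory lists share Pdcd1, Cd200 and Btla.

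The recipient difference of 2 named genes went one way in CD62L- cells and the other way in CD62L+ cells, without overlap of the libraries in either subset. Within a single subset, chance gives such a separation in 10% of comparisons of 3 with 3 libraries. These 2 genes were found by searching the named genes for this pattern. Cd160 was 41.4 ± 3.5 in Batf3-/- and 82.5 ± 7.8 CPM in WT CD62L- cells, and 19.1 ± 2.8 and 9.4 ± 2.6 CPM in CD62L+ cells. The difference of the differences was -2.02 on the log2 scale and was not called (adjusted p = 0.135). It was -0.8 for Il21 (adjusted p = 1), also not called.

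B cell transcripts were higher in CD62L+ than in CD62L- cells, with 13 of 16 markers called in the average over recipients. Summed without Ighm they averaged 171 ± 22.4 CPM in naive, 581 ± 79.9 in WT CD62L+, 77.49 ± 6.35 in WT CD62L-, 660.1 ± 76.3 in Batf3-/- CD62L+ and 150.1 ± 26.6 in Batf3-/- CD62L- cells, with Cd74 at 277 ± 34 and 318 ± 29 CPM in the CD62L+ groups and Ighm between 611 and 953 CPM in all groups. Library scaling moves all genes alike. It is argued against because camera set the markers apart from other genes in this average (adjusted p = 5.69e-06 with an estimated correlation). RLE size factors gave a median log2 fold change of -2.63, against -2.64. They moved the median of all genes by only 0.012, so this value could hardly have changed and tests little. Dendritic cells or macrophages as the source are argued against by a median of -0.2 over 15 of their markers, although 11 of these lay below 0 and fry called the list (adjusted p = 0.0157). B cells, or B cells bound to T cells, among the CD62L+ cells may explain it, although the sort for donor CD45.1+ T cells should remove them. Mean Ighm was also not higher in CD62L+ than in CD62L- cells of either recipient. A difference in the T cells themselves was not tested and stays open.

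Other splits of the libraries test whether chance can give as many called genes. Averaged over recipients, the subset difference called 590 genes, and 1 of 100 splits gave as many, the real one, with 44 the highest of the others. That share lies under 0.05 and argues against chance. The splits ignored the replicate number, by which the libraries also differed, so they are not fully exchangeable and the share is approximate. The same held for the recipient difference averaged over subsets, with 88 genes, 1 of 100 splits and 2 as the highest other. For each comparison of 2 groups 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts and highest others were 244 and 0 for the subsets in WT recipients, 100 and 0 in Batf3-/- recipients, 10 and 1 for the recipients in CD62L- cells and 1 and 0 in CD62L+ cells. Against naive cells they were 6004 and 1 for WT CD62L-, 5430 and 0 for WT CD62L+, 5843 and 1 for Batf3-/- CD62L- and 6020 and 1 for Batf3-/- CD62L+ cells. For the test of whether the subset difference depended on the recipient, 100 of 100 splits gave at least its 0 genes, which a count of 0 fixes in advance, so the splits say nothing about chance there. The highest other there was 88, in the split that exchanges the recipients in one subset and so measures the recipient difference itself, and the next highest was 2.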

How the results depend on the processing

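The fit without the 2 libraries that stood apart (the third WT CD62L- and the third Batf3-/- CD62L- ones) and the fit without ribosomal RNA locus genes were chosen after the data were seen.

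None of the values for genes taken by the naming rule reversed under any alternative run. Of 535 such values, 534 kept their side of the threshold with RLE size factors, 525 without a filter, 527 with DESeq2, 518 with voom, 526 with a replicate block, 533 without ribosomal RNA locus genes and 501 without the 2 libraries that stood apart. With fits of the compared groups only, 489 of 530 did, with the stricter filter 529 of 529, and with each library left out in turn 3427 of 3768, where 336 fell short of the threshold. RLE size factors moved the median of all genes by at most 0.026 on the log2 scale in the primed comparisons. The counts against naive cells stayed within 1.5 times under every alternative run.

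The counts between primed groups depended on the test. The subset difference in WT recipients called 529 genes with the replicate block, 824 with DESeq2, 476 with voom and 121 with the compared groups only, against 244. In Batf3-/- recipients these were 197, 432, 335 and 26, and 55 without the 2 libraries that stood apart, against 100. Averaged over recipients the first 3 gave 985, 1259 and 1099, against 590. The recipient difference in CD62L- cells gave 74, 431, 79 and 0 genes under the same 4 alternatives, against 10. In CD62L+ cells it gave 32, 142, 70 and 0, with 5 without a filter, 5 with the stricter filter and 2 without the 2 libraries, against 1. In the fits giving 0, 1082 and 1222 genes had an unadjusted p under 0.05. Averaged over subsets it gave 201, 620 and 327 genes with block, DESeq2 and voom and 38 without the 2 libraries, against 88. The interaction called 1 gene without a filter, 1 with the block, 36 with DESeq2, 1 with voom and 2 without the 2 libraries, against 0 with edgeR on all libraries (860 at an unadjusted p under 0.05). DESeq2 called all of the 244, 100, 590, 10, 1 and 88 genes. Fits of the compared groups only have fewer libraries, and the cause of the other shifts was not tested.

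With each library left out in turn, the counts ran from 121 to 265 (subsets, WT recipients), 32 to 51 (subsets, Batf3-/- recipients), 388 to 600 (subsets, average), 4 to 31 (recipients, CD62L- cells), 0 to 1 (recipients, CD62L+ cells), 36 to 132 (recipients, average) and 0 to 2 (interaction). The upper ends 265, 600, 31 and 132 came without the first WT CD62L- library. The results name each library whose removal moved a count by more than 1.5 times. Against naive cells the counts ran from 4726 to 5402 (WT CD62L-), 4090 to 4781 (WT CD62L+), 4574 to 5212 (Batf3-/- CD62L-) and 4643 to 5125 (Batf3-/- CD62L+).

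Of the lists called with camera, an estimated correlation kept 5 of 9 (subsets, WT), 2 of 8 (subsets, Batf3-/-), 6 of 9 (subsets, average), 4 of 9 (recipients, CD62L-), 5 of 13 (recipients, CD62L+), 5 of 11 (recipients, average) and 1 of 5 (interaction), and against naive cells 14 of 17, 14 of 18, 13 of 17 and 15 of 19. Fry kept 7, 6, 9, 6, 7, 9 and 0 of the first 7. Depth limits Batf3 and Il13, with 49 and 24 counts over the 15 libraries, and Il5, with none.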

Other observations

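The tests of handling stress, naive cells, chance numbering, ribosome biogenesis genes and the size of the subset difference were chosen after the results were seen.

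The remaining lists against naive cells gave the following in WT CD62L- cells. Of the glycolysis list 11 of 15 genes rose (camera adjusted p = 3.86e-09, 0.00312 with an estimated correlation), of the early T cell receptor genes 11 of 17 rose and 1 fell (3.95e-08, 0.0346), and of the BCL2 family and Fas list 6 of 14 rose and 1 fell (3.01e-05, 0.00244). Of the Th17 list 4 of 9 rose (0.000475, 0.0261). Lists not called were cholesterol synthesis (3 higher and 7 lower of 19, adjusted p = 0.121), CD8 and NK markers (1 and 4 of 9, 0.196), stromal and endothelial markers (2 of 6 higher, 0.293), plasma cell markers (2 of 7 higher, 0.528), dendritic cell and macrophage markers (1 and 3 of 15, 0.74) and heat shock (3 and 2 of 10, 0.76). Of the neutrophil list 2 genes had enough counts, too few for a list test, and neither was called.

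Interferon response genes were higher in cells from Batf3-/- recipients, with a mean log2 difference of 0.6 over the list. A single library as the cause is argued against by a mean of 0.57 to 0.64 without any 1 of the 12 libraries. Unprimed naive cells among them are argued against by a median implied naive share of -0.33% over 97 genes high in naive cells (quartiles -2.7 and 1.9), where the interferon genes would need 11.8 and 13.4% in CD62L- and CD62L+ cells. Handling stress, read from heat shock genes, cannot be told apart. With group means removed the lists correlated at r = -0.73 over 12 libraries (Spearman -0.71, permutation p = 0.00774 and 0.0127, -0.92 without the 2 farthest). The permutation shuffled the 12 values freely. Removing group means ties them within groups, and libraries of a number shared features, so these p-values are approximate. With replicate number means also removed the correlation was -0.01, a form chosen after the first value was seen. A response of the T cells to the recipient may also explain it and stays untested.

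Libraries with the same replicate number shared features across groups, and 1349 genes differed by number. None of 19 random renumberings within groups gave as many genes, with 548 the highest. That is too few renumberings for a share under 0.05, so they do not settle whether chance numbering explains the count. With the ribosomal RNA share as a covariate edgeR called 0 genes (1424 at an unadjusted p under 0.05, no other tool run), but 88.3% of the variance of that share within groups followed the number, so the share and other causes tied to the number cannot be told apart. The strongest genes included Rps2, Cd3e, Atxn2l and Rpl30. Each of the 15 libraries correlated most with libraries of its own number, at 0.02 to 0.11 after group means were removed. Pairs of different numbers lay at -0.11 to 0.03. The numbers were left out of the main fit by a rule that all such pairs pass 0.1, which 4 of 30 did. That cutoff was a choice and does not show that the numbers are without effect, so the replicate block is given beside the main fit. No biological explanation was tested.

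Ribosome biogenesis genes were tested because genes of this theme had been seen among the called ones. The seen genes were left out of the list, but it still held 10 genes that were called between the subsets. The libraries are the same, so the test is not independent of those calls. Over 43 tested genes the level may be higher in cells from Batf3-/- recipients, with a mean log2 difference of 0.17, 38 genes above 0, 0 of them called, and an exact permutation p = 0.005 (two-sided), the smallest that 400 arrangements can give. In CD62L- cells it may be lower, with a mean of -0.28, 39 genes below 0, 10 of them called, and an exact permutation p = 0.005. Summed levels were 3541 ± 117 CPM in naive, 3229 ± 47.7 in WT CD62L+, 2830 ± 75.6 in WT CD62L-, 3759 ± 36.6 in Batf3-/- CD62L+ and 3044 ± 65.9 in Batf3-/- CD62L- cells.

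The subset difference may be smaller in Batf3-/- recipients. Over 577 genes its mean in the called direction was 1.19 in WT and 0.99 in Batf3-/- recipients on the log2 scale, a difference of 0.2, with 392 genes smaller. An exact permutation p = 0.12 over 400 arrangements leaves this open.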
